A study of Mus musculus with 11 samples.

How the data were processed

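Processed tables and labels of the series were used, and no raw reads were read. Per the labels, RNA of primary mesenchymal stromal cells from bone marrow was extracted with the RNeasy mini plus kit, and 8.7 ng of total RNA entered library preparation with NEBNext end repair, dA-tailing and quick ligation modules. The submitters' processing notes name Trim Galore, STAR, HTSeq and DESeq2 and the build GRCm39, and the versions of these tools are not given in the sources used here. Each of the 2 deposited tables held 1 knockout with the same 4 wild type libraries: 19259 genes for the ANXA2 knockout and 19801 for the ANXA5 knockout, with 18712 identifiers in both. The wild type reads recovered from both were the same in 100% of shared genes. Genes with 0 reads in a knockout library were not in the tables. Among wild type libraries, genes with 0 reads were present only for library 4 in the ANXA2 table (188 genes) and library 3 in the ANXA5 table (412 genes). A gene with 0 reads in all libraries of a group was thus absent and could not be called.

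The signal of each gene and library was, in the tables the authors deposited, the read count divided by a DESeq2 size factor of the library. The values multiplied by that factor gave whole reads in 100% of cases within 0.001, and these recovered reads were used where reads are named. The log2 fold changes the authors deposited came from DESeq2 and are knockout minus wild type, as the signal columns show. The score column of the deposited tables, the Wald statistic per the file headers, had the opposite sign of the fold change in 100% of genes and was not used. The p-values and adjusted p-values the authors deposited were those of DESeq2 per the file headers, and an adjusted p was present for 17374 genes of the ANXA2 and 15949 of the ANXA5 table. Size factors ranged from 0.8587 to 1.206 in the ANXA2 and from 0.7775 to 1.221 in the ANXA5 table. The most abundant gene of a library, Gsn or Col3a1, held 3.29 to 5.23% of its reads, and the 10 most abundant genes 12.6 to 16.2%.

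Groups were read from the labels, and 0 sample columns were left out. The columns of the ANXA2 knockout were matched to the group only, because their numbers are not those of the titles. Because the values are counts divided by size factors, the test written for such values was used: limma-trend on log2 (value + 1), over genes with a value of at least 10 in as many libraries as the smaller group has. P-values were two-sided and adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold. Gene lists were tested with camera of limma at a preset inter-gene correlation of 0.01, with at least 5 tested genes and without the targeted gene, and adjusted over the lists. The 43 lists were hand-made from known functions, and 41 were tested. edgeR quasi-likelihood, DESeq2 and limma-voom fits used the recovered reads. The difference of both knockouts was tested with edgeR in a joint fit of all libraries. Exact permutation tests over libraries were used for the targeted genes. The tests, lists and alternatives were fixed before the data were examined, apart from those named as later choices. Fits ran in R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0.

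The genes named were the targets and their annexin and S100 relatives, the 8 highest and 8 lowest fold changes among called genes with separate groups and a mean of at least 50, and the 2 smallest adjusted p in each direction. Up to 4 members of each called list and 2 of other lists were added by smallest p, and where fewer than 5 genes passed in a direction the 5 smallest unadjusted p were given. Chromosomes and distances came from GENCODE vM21 on GRCm38, which is not the build of the submitters. It matched 99.76% of the tested identifiers of the ANXA2 and 99.77% of those of the ANXA5 comparison, and it was used for nothing else.

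Alternatives were TMM scaling, edgeR, DESeq2, limma-voom, pseudocounts of 0.5 and 5 in place of 1, no filter, a minimum of 50, a log2 fold change of at least 1, an adjusted p under 0.1 for the overlap, an estimated inter-gene correlation, distances of 2 and 10 Mb in place of 5, and leaving out each library in turn. In simulated tables of unchanged libraries with 200 changed genes, limma found 51% of genes changed 2-fold and 91% of those changed 4-fold in the ANXA2 layout, and 67% and 89% in the ANXA5 layout, with 9 and 10 false calls. DESeq2 found 75% and 92%, and 71% and 90%, with 55 and 36 false calls. A simulated shift of 1 list was found by camera in both layouts, and 0 of 40 unchanged lists were called. The simulated genes varied independently of each other, so this could not show how often camera calls unchanged lists whose genes move together. Tables of reads for genes outside the deposited ones, alignment rates and strand were not available and were left out. Results for a few genes are not reported here.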

Results

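RNA was sequenced from primary mesenchymal stromal cells of mouse bone marrow, adherent cells that can form bone, fat and cartilage and that support blood formation. The 11 untreated libraries fell into 3 genotypes: 4 were wild type C57/BL6, 3 carried a knockout of ANXA2 and 4 a knockout of ANXA5. Both targets are annexins, proteins that bind phospholipid membranes in the presence of calcium. Each knockout was set against the wild type, and the effects of both knockouts were then compared. The labels do not state separate animals or cultures for the libraries of a group, so the p-values measure the spread between these samples, which may be technical in part. The reads counted over the genes of the deposited tables came to 27.4, 32 and 26.1 M in ANXA2 knockout libraries 1, 3 and 4, and to 23.3, 29.1, 23.5 and 27.2 M in wild type libraries 1 to 4. ANXA5 knockout libraries 1 to 4 held 35.7, 27, 27.6 and 35.3 M. The ANXA2 knockout libraries are named by the numbers of their columns, which differ from those of the titles. Each knockout was scaled together with the wild type in a table of its own, so the wild type mean of a gene differs between the comparisons.

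Xist, the RNA that silences an X chromosome in female cells, varied within every group. In the table of the ANXA2 knockout it stood at 652, 226 and 203 normalised reads in the knockout libraries and at 1829, 1997, 1.16 and 0.959 in wild type libraries 1 to 4. In the table of the ANXA5 knockout, knockout libraries 1 to 4 held 783, 2.07, 1676 and 528 normalised reads of Xist. Replicates of a group differed by more than sampling noise in every pair, with a chi-square per degree of freedom of 29.4 to 106. Their log2 values correlated at 0.972 to 0.987 across genes, which are not independent replicates.

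The targeted genes were examined first. Anxa2 (ENSMUSG00000032231.15, chromosome 9) fell in the ANXA2 knockout to 28.6% of the wild type level, with 8542 ± 1691 normalised reads (SD, n = 3) against 29822 ± 1354 (SD, n = 4). The log2 fold change was -1.82 (SE 0.15, 95% interval -2.16 to -1.48, limma adjusted p = 0.00191). Anxa5 (ENSMUSG00000027712.14, chromosome 3) fell in the ANXA5 knockout to 9.24%, with 2359 ± 57.4 normalised reads (SD, n = 4) against 25529 ± 1704 (SD, n = 4). Its log2 fold change was -3.43 (SE 0.0796, 95% interval -3.61 to -3.26, limma adjusted p = 1.91e-08). The knockout and wild type libraries did not overlap for either target, and both exact permutation tests gave a two-sided p of 0.0286, the smallest these groups allow. Neither annexin passed the test in the other knockout. Anxa5 stood at 24289 ± 3854 (n = 3) against 23270 ± 1645 (n = 4) in the ANXA2 knockout, a log2 difference of 0.05 (95% interval -0.289 to 0.393, exact permutation p = 0.714). Anxa2 stood at 32835 ± 1507 (n = 4) against 32719 ± 1347 (n = 4) in the ANXA5 knockout, a log2 difference of 0.00 (95% interval -0.218 to 0.228, exact permutation p = 0.886). The values are totals per gene, and the labels do not say which part of either gene was removed.

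**Figure D1:**
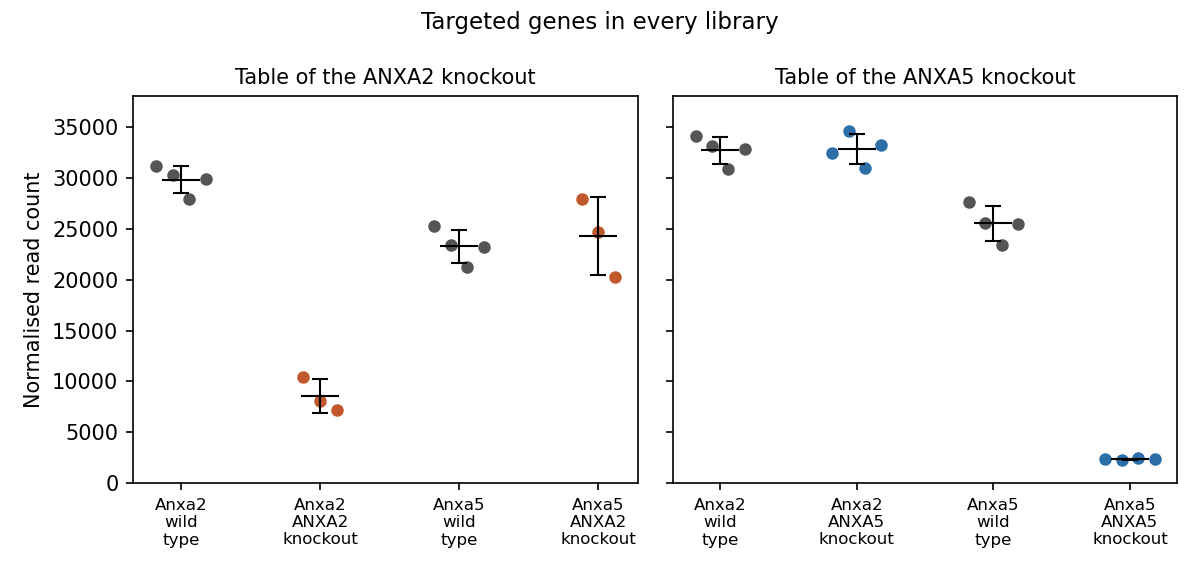
Normalised read counts of Anxa2 and Anxa5 on a linear axis in the tables of the ANXA2 knockout (left) and the ANXA5 knockout (right), with points for libraries and bars for the mean ± SD. Anxa2 lies between 7159 and 10427 in the 3 ANXA2 knockout libraries and between 27947 and 31163 in the wild type, and Anxa5 lies between 2295 and 2426 in the 4 ANXA5 knockout libraries.

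In the ANXA2 knockout, 18 of 16123 tested genes changed, 9 upward and 9 downward. Rpl29 (ENSMUSG00000048758.15), a protein of the large ribosomal subunit, fell from 1339 ± 149 to 139.7 ± 33.3 normalised reads (SD, n = 4 and 3; log2 -3.27, SE 0.17, limma adjusted p = 0.000193). Abhd14b (ENSMUSG00000042073.16), a lysine deacetylase of the alpha/beta hydrolase family, fell from 485 ± 86.4 to 67.5 ± 20.3 (log2 -2.85, SE 0.22, limma adjusted p = 0.00132). Plac9a (ENSMUSG00000095304.10), which encodes a small secreted protein, rose from 3201 ± 428 to 15599 ± 936 (log2 2.29, SE 0.124, limma adjusted p = 0.000193). Tmem254a (ENSMUSG00000072676.13), a transmembrane protein gene on the same chromosome 14, rose from 732 ± 103 to 2571 ± 297 (log2 1.82, SE 0.137, limma adjusted p = 0.00132). All 18 genes had knockout libraries entirely outside the range of the wild type libraries.

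The remaining falls included Slc35g2 (ENSMUSG00000070287.4), a solute carrier gene, with a log2 fold change of -2.72 and Coro2b (ENSMUSG00000041729.16), which encodes an actin-binding coronin (-1.84). Fam219b (ENSMUSG00000032305.16) fell by 1.43 on the log2 scale, and Glb1 (ENSMUSG00000045594.11), the lysosomal beta-galactosidase, by 0.92, from 1323 ± 84.6 to 696 ± 34.5 normalised reads. The limma adjusted p of these 4 genes lay between 0.00456 and 0.0208. The remaining rises included Erdr1 (ENSMUSG00000095562.9), at 496 ± 205 against 2.02 ± 1.47 normalised reads (log2 7.48, limma adjusted p = 0.00111), and Lrmda (ENSMUSG00000063458.14), linked to melanocyte differentiation, at 72.6 ± 14.8 against 8.97 ± 4.66 (2.96, 0.0225). The immunoglobulin segment Igkv5-43 (ENSMUSG00000094433.3) rose by 3.20 and the antisense transcript Rab10os (ENSMUSG00000079179.10) by 1.08 on the log2 scale. Beside the segment, Igkc ranged from 6624 to 10460 against 3658 to 6002 and Jchain from 1291 to 1984 against 529.8 to 984.3, chosen after their values were seen and not past the threshold (limma adjusted p = 0.51 and 0.446). The other 4 calls were predicted genes, 3 of them higher and 1 lower, named here after their values were seen: Gm11868 (3.95), Gm47283 (2.31), Gm21104 (1.51) and Gm42047 (-1.13). Rpl29, Erdr1, Plac9a, Tmem254a, Gm21104 and the immunoglobulin segment have near-identical copies, and the counts do not state strand, so the values of these genes and of Rab10os are uncertain. Gm47283 is placed on chromosome Y but was also read in wild type libraries 1 and 2, with high Xist (107 and 139 normalised reads), so its values are uncertain too.

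At the unadjusted level 1401 genes (8.69%) had a p under 0.05, and 1482 genes (9.19%) had groups that did not overlap, where chance gives 5.71%. All 18 calls were also made by edgeR (21 genes), by DESeq2 (107 genes, 64 higher) and in the authors' deposited table (103 genes, 66 higher and 37 lower). With Xist as a covariate, an alternative added after the data were seen, 284 genes passed, 248 of them higher. The count was 8 without knockout library 3, 11 without wild type library 2 and 10 without wild type library 4, and 7 of the 14 named genes that passed lost their call without at least 1 library.

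Position along the genome was taken from a GRCm38 annotation that matched 99.76% of the tested identifiers. Of the 16 called genes with a position other than Anxa2, 7 (43.8%) lay on chromosome 9, the chromosome of Anxa2, against 5.62% of tested genes (Fisher's exact p = 1.27e-05, a comparison made after the calls were seen), and all 7 were lower in the knockout. They included Rpl29, Abhd14b, Slc35g2, Coro2b, Fam219b and Glb1, and all 7 started between 11.9 Mb before and 44.9 Mb after Anxa2. Within 5 Mb of Anxa2, 0 of 82 tested genes passed the limma threshold (Fisher's exact p = 1), while 10 of 82 (12.2%) had an unadjusted p under 0.01 against 1.82% of other genes (Fisher's exact p = 3.04e-06). Chromosome 9 held 30 of the 101 called genes with a position (29.7%) in the authors' deposited table.

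**Figure D2:**
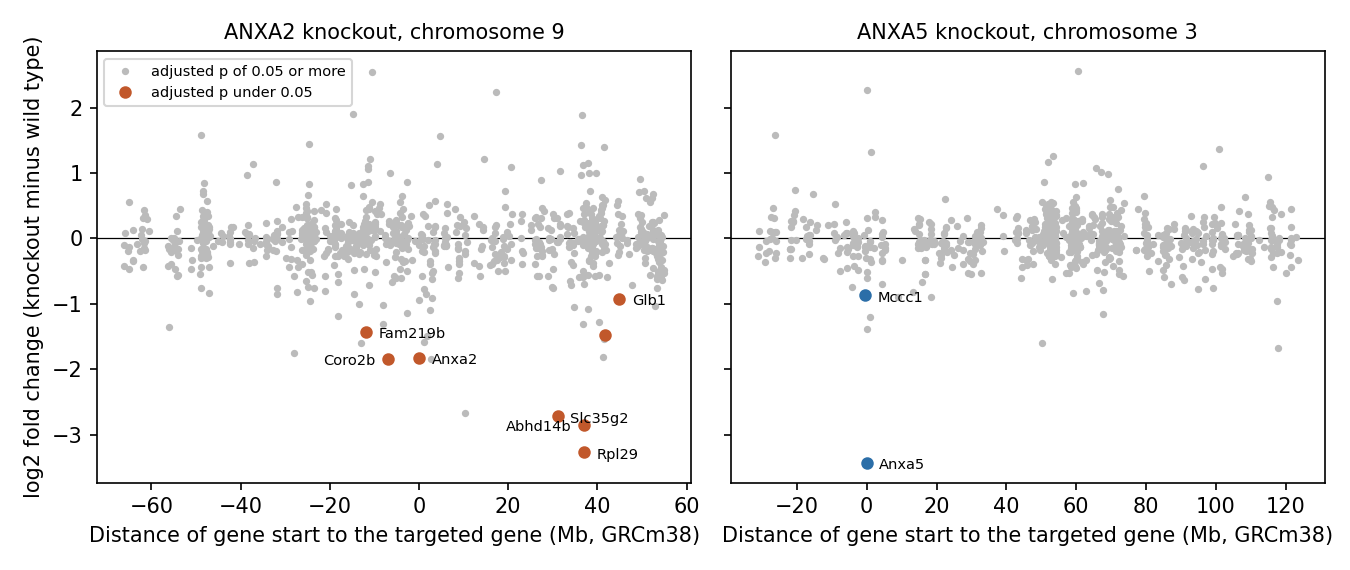
Log2 fold change (knockout minus wild type) of the tested genes on the chromosome of the targeted gene, against the distance in Mb of the gene start from the targeted gene in GRCm38, with 1 point per gene and coloured points for a limma adjusted p under 0.05. On chromosome 9 the coloured points besides Anxa2 lie between -11.9 and 44.9 Mb and all have negative fold changes, and on chromosome 3 Mccc1 lies 0.49 Mb from Anxa5.

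The 10 measured mitochondrially encoded genes, which code for subunits of the respiratory chain and ATP synthase, fell as a list in the ANXA2 knockout (camera adjusted p = 5.48e-10; adjusted p = 0.518 with an estimated correlation). Their median log2 fold change was -0.71, 0 of 10 lay above 0, and 9 fell adjusted over the list alone. mt-Co1 stood at 7178 ± 1738 against 14922 ± 4270 normalised reads (log2 -1.04, limma adjusted p = 0.392) and mt-Nd4 at 1550 ± 208 against 2412 ± 417 (-0.63, 0.423). The cholesterol synthesis list fell too (camera adjusted p = 4.22e-07; adjusted p = 0.518 with an estimated correlation), with a median of -0.31, 3 of 22 members above 0 and 3 falls adjusted over the list alone. Its score was -0.601, -0.139 and -0.21 in knockout libraries 1, 3 and 4 and -0.0612 to 0.0917 in the wild type. Idi1, the isopentenyl diphosphate isomerase, stood at 182 ± 32.5 against 294 ± 40.2 (-0.69, limma adjusted p = 0.459), and the sterol desaturase gene Sc5d at 851 ± 114 against 1147 ± 93.1 (-0.44, 0.476). Ribosomal protein genes fell as a list (median -0.15, 3 of 22 above 0, camera adjusted p = 0.0107; adjusted p = 0.668 with an estimated correlation), with Rpl4 at -0.29 and Rpl7 at -0.29. The ribosomal call was lost without 4 of the 7 libraries (limma camera adjusted p = 0.436 without knockout library 1). Wild type library 3 was itself low, with a ribosomal list score of -0.376 against 0.101 to 0.168 in the other wild type libraries.

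Targets of NF-kB, the transcription factor of inflammatory signalling, rose as a list in the ANXA2 knockout (camera adjusted p = 4.22e-07; adjusted p = 0.518 with an estimated correlation). All 16 had a fold change above 0, the median was 0.39, and 2 rose adjusted over the list alone. The list score was 0.546, 0.216 and 0.344 in knockout libraries 1, 3 and 4, while wild type library 3 stood at 0.285 and the other wild type libraries at -0.105 to -0.0781. Icam1, a leukocyte adhesion molecule, stood at 15079 ± 2291 against 9147 ± 1691 normalised reads (0.73, limma adjusted p = 0.393) and Nfkbia, the inhibitor of NF-kB, at 23815 ± 3072 against 15709 ± 2352 (0.60, 0.463). Immediate early genes, transcribed within minutes of a stimulus, rose as a list (median 0.47, 20 of 20 above 0, camera adjusted p = 5.4e-07; adjusted p = 0.542 with an estimated correlation). The list score was 0.93, 0.39 and 0.336 in knockout libraries 1, 3 and 4, with wild type library 3 at 0.494 and the other wild type libraries at -0.256 to -0.0972. Egr3 stood at 587 ± 69.8 against 251 ± 124 (1.36, limma adjusted p = 0.462), and Klf4 at 16369 ± 2554 against 8268 ± 4142 (1.10, 0.518). The TGF-beta and BMP target list rose (median 0.28, 15 of 18 above 0, camera adjusted p = 0.000643; adjusted p = 0.518 with an estimated correlation), with Id1 at 1055 ± 41.6 against 865 ± 32.7 (0.29) and Id3 at 16260 ± 3440 against 11320 ± 1310 (0.51). Its call was lost without knockout library 1 (limma camera adjusted p = 0.0566). The interferon response list (median 0.17, 21 of 25 above 0, camera adjusted p = 0.0298; adjusted p = 0.63 with an estimated correlation) and the antigen presentation list (0.14, 15 of 17, 0.0301; adjusted p = 0.617 with an estimated correlation) rose as well. Oas2 had a log2 fold change of 0.47 and H2-D1, a class I histocompatibility gene, of 0.34. The interferon call was lost without 4 of the 7 libraries, at a camera adjusted p of up to 0.333 (without wild type library 4), and the antigen presentation call without 3, at up to 0.784 (without knockout library 4). The antigen presentation score was -0.0393, 0.0993 and 0.393 in knockout libraries 1, 3 and 4 and -0.108 to 0.0511 in the wild type, and library 4 also had the highest scores of macrophage (0.556) and neutrophil (0.927) markers of the 7 libraries.

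Genes of the matrix rose as lists in the ANXA2 knockout. Collagens and fibrous matrix genes had a median log2 fold change of 0.23 with 23 of 26 above 0 (camera adjusted p = 0.013; adjusted p = 0.542 with an estimated correlation), including Eln, which encodes elastin, at 13668 ± 4189 against 7643 ± 1210 normalised reads (0.80, limma adjusted p = 0.471). The call was lost without knockout library 3 (limma camera adjusted p = 0.0882). The list score was 0.294, 0.417 and 0.12 in knockout libraries 1, 3 and 4, and -0.254, -0.152, 0.222 and 0.184 in wild type libraries 1 to 4. Matrix proteases and their inhibitors had a median of 0.16 with 15 of 18 above 0 (camera adjusted p = 0.0447; adjusted p = 0.542 with an estimated correlation), including the aggrecan-cleaving protease Adamts4 at 5807 ± 2289 against 2812 ± 697 (0.98). Their call was lost without 5 of the 7 libraries (limma camera adjusted p = 0.295 without knockout library 1). Glycolysis and hypoxia genes rose (median 0.20, 23 of 25 above 0, camera adjusted p = 0.000319; adjusted p = 0.542 with an estimated correlation), and 1 rose adjusted over the list alone. Pgk1, the phosphoglycerate kinase, stood at 2583 ± 43.4 against 1900 ± 162 (0.45, limma adjusted p = 0.335). Genes of the unfolded protein response rose (0.23, 15 of 20 above 0, camera adjusted p = 0.00779; adjusted p = 0.542 with an estimated correlation), with the endoplasmic reticulum gene Sdf2l1 at 1779 ± 287 against 1268 ± 72.6 (0.48). Without knockout library 1 the camera adjusted p of that list was 0.184.

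Lists tied to the known roles of annexins at membranes also rose. Membrane repair and exocytosis genes had a median of 0.16 with 16 of 20 above 0 (camera adjusted p = 0.0221; adjusted p = 0.518 with an estimated correlation), with Pdcd6, a calcium-binding adaptor, at 2500 ± 90.4 against 2088 ± 105 normalised reads (0.26). Extracellular vesicle genes had a median of 0.12 with 19 of 21 above 0 (camera adjusted p = 0.0328; adjusted p = 0.542 with an estimated correlation), with the sphingomyelinase Smpd3 at 4725 ± 1189 against 2858 ± 830 (0.75). Calcium handling genes had a median of 0.23 with 16 of 21 above 0 (camera adjusted p = 0.0306; adjusted p = 0.518 with an estimated correlation), with the calcium pump gene Atp2a2 at 0.33 and the sodium-calcium exchanger Slc8a1 at -0.75. The calcium score was 0.167 to 0.191 in the knockout and -0.192, -0.093, 0.136 and 0.149 in wild type libraries 1 to 4. Wild type libraries 1 and 2 were thus the lower ones, as for collagens. They were also the wild type libraries with high Xist, at 1829 and 1997 normalised reads against 1.16 and 0.959 in libraries 3 and 4. Whether the scores of these lists follow that division was not tested. Without 1, 3 and 4 of the 7 libraries these calls were lost, with the highest limma camera adjusted p, 0.194, 0.237 and 0.0859, without knockout library 1. NRF2 targets of the oxidative stress response rose (median 0.11, 14 of 18 above 0, camera adjusted p = 0.0462; adjusted p = 0.518 with an estimated correlation), and 2 rose adjusted over the list alone. The members with the smallest p were metallothioneins, which bind zinc and copper: Mt1 stood at 14208 ± 4739 against 6352 ± 1770 (1.14, limma adjusted p = 0.392) and Mt2 at 4292 ± 1359 against 2136 ± 652 (0.998, 0.471). The NRF2 call was lost without 5 of the 7 libraries, at a camera adjusted p of up to 0.212 (without knockout library 4).

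Annexins and their S100 partners did not change as a list in the ANXA2 knockout (13 tested, camera adjusted p = 0.21), and 0 passed limma, 1 with an unadjusted p under 0.05. S100a10, the partner of ANXA2 in a heterotetramer, stood at 7619 ± 681 against 6770 ± 1121 normalised reads (0.18, limma adjusted p = 0.72). S100a11 stood at 9699 ± 2070 against 7258 ± 764 (0.40, 0.564) and Anxa1 at 47496 ± 9083 against 38541 ± 1460 (0.29, 0.617). Stromal identity markers had a median of 0.10 (limma camera adjusted p = 0.0555), with Itga5 at 0.80 and Thy1 at 0.39. Lineage lists did not pass: the osteogenic list had a camera adjusted p of 0.21 (median 0.22), the adipogenic list 0.122 (0.45) and the chondrogenic list 0.751, with a median of -0.10 but a mean of 0.01 and an upward test. Markers of other cell types did not pass either, with a camera adjusted p of 0.0983 for macrophages and monocytes (median 0.19), 0.122 for neutrophils (0.20), 0.0555 for lymphocytes (-0.09), 0.21 for erythroid cells and megakaryocytes (-0.22), 0.278 for endothelium (0.24) and 0.129 for skeletal muscle (-0.65).

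Of the remaining lists in the ANXA2 knockout, cytokines and chemokines had a camera adjusted p of 0.0539, with Cx3cl1 at 0.57 and Cxcl2 at 0.71. Focal adhesion and integrins had 0.0555, the Wnt pathway 0.092, endosome and lysosome 0.127, immunomodulatory mediators 0.129 and plasminogen and coagulation 0.174, where the urokinase receptor gene Plaur had a log2 fold change of 0.38. Nuclear oxidative phosphorylation genes and actin and contractile genes each had a camera adjusted p of 0.174, cell cycle and DNA replication and Hox and positional genes each 0.29. Apoptosis and efferocytosis had 0.307, angiogenic factors 0.364, mitochondrial biogenesis and dynamics 0.622 and p53 and senescence 0.967, where Glb1 was the 1 member that fell. Over all 41 tested lists, 16 passed camera with the preset correlation, 13 upward and 3 downward. With a correlation estimated for each list camera called 0 (lowest adjusted p = 0.518, and 0 at an unadjusted p under 0.05), and fry called 0 (lowest adjusted p = 0.232). Of 757 distinct genes in these lists, 1 passed limma over all genes, 98 had an unadjusted p under 0.05, edgeR called 1 and DESeq2 called 6, against 18 list entries that passed adjusted over the list alone. In all, 5 of the 16 lists kept their call without each library in turn.

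In the ANXA5 knockout, 5 of 16224 tested genes changed, 3 upward and 2 downward. Besides Anxa5, the gene that fell was Mccc1 (ENSMUSG00000027709.10), a subunit of the methylcrotonyl-CoA carboxylase of leucine breakdown, at 339 ± 26.9 against 621 ± 56.8 normalised reads (SD, n = 4 and 4; log2 -0.87, SE 0.104, limma adjusted p = 0.0266). The 3 that rose were variable segments of immunoglobulin genes. Igkv8-30 (ENSMUSG00000076577.3) stood at 276 ± 86.8 against 16.3 ± 3.8 (3.96, SE 0.271, limma adjusted p = 0.000384), Ighv1-81 (ENSMUSG00000094689.2) at 285 ± 129 against 22.1 ± 8.23 (3.61, SE 0.331, 0.003), and Ighv8-8 (ENSMUSG00000104452.2) at 114.5 ± 27.7 against 18.8 ± 1.39 (2.51, SE 0.212, 0.00182). Such segments resemble each other closely, so their counts are uncertain. In the authors' deposited table Ighv8-8 was also higher in the ANXA2 knockout (log2 1.46, adjusted p = 0.00716), and Ighv1-81 did not pass there (2.05, adjusted p = 0.157). Igkv8-30 was lower in the ANXA2 than in the ANXA5 knockout in the joint edgeR fit (-3.97, edgeR adjusted p = 0.000248). Other antibody genes, chosen after their values were seen, had higher values in the knockout without passing the test. Ighg1 stood at 189.7, 1181, 474.6 and 578.9 normalised reads in knockout libraries 1 to 4 and at 63.73, 45.37, 0 and 4.208 in the wild type (limma adjusted p = 0.217). Igkc ranged from 8109 to 14540 against 4040 to 6570 (limma adjusted p = 0.231), and Jchain, the joining chain of plasma cells, from 1006 to 2882 against 585.2 to 1076 (limma adjusted p = 0.418). All 5 called genes had knockout libraries entirely outside the wild type range, while Jchain overlapped it.

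The genes with the next smallest p did not pass. Emp1, an epithelial membrane protein gene, stood at 15500 ± 1507 against 25233 ± 2053 normalised reads (log2 -0.70, limma adjusted p = 0.117), and Afap1l1, an actin filament associated gene, at 264 ± 58.7 against 102 ± 26.9 (1.38, 0.117). Zmat3, a target of p53 on chromosome 3 with Anxa5, stood at 99.4 ± 8.99 against 167 ± 12.1 (-0.74, 0.173), and the antisense transcript Rab10os at 579 ± 57.3 against 341 ± 38.2 (0.76, 0.117). Trdv4, a variable segment of the T cell receptor, stood at 4.04 ± 0.706 against 15.2 ± 3.09 (-1.68, 0.173). In the authors' deposited table Emp1 (adjusted p = 9.75e-08) and Afap1l1 (adjusted p = 1.56e-06) were past the threshold. In total 1936 genes (11.9%) had an unadjusted p under 0.05, and 1033 (6.37%) had groups that did not overlap, where chance gives 2.86%. All 5 calls were also made by edgeR (5 genes), by DESeq2 (278 genes, 156 higher) and in the authors' deposited table (281 genes, 158 higher and 123 lower). The count rose to 32 without wild type library 4 and to 8 without knockout library 3, and Mccc1 lost its call without 6 of the 8 libraries in turn (limma adjusted p = 0.108 to 0.169).

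Mccc1 started 0.49 Mb from Anxa5 on chromosome 3. Within 5 Mb of Anxa5, it was the 1 of 47 tested genes (2.13%) that passed the limma threshold, against 0.0186% of other genes (Fisher's exact p = 0.0116). At an unadjusted p under 0.01, 8 of 47 (17%) passed against 3.19% of other genes (Fisher's exact p = 0.000117). Chromosome 3 as a whole held 1 of the 4 calls with a position besides Anxa5 (25%), against 4.98% of tested genes (Fisher's exact p = 0.185). In the authors' deposited table it held 26 of the 280 called genes with a position (9.29%), against 4.93% of genes with an adjusted p.

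Markers of endothelial cells, macrophages and monocytes, neutrophils, and erythroid cells and megakaryocytes rose as lists in the ANXA5 knockout, and lymphocyte markers did not pass. The 17 endothelial genes had a median log2 fold change of 1.18, 15 of them above 0 (camera adjusted p = 4.65e-07; adjusted p = 0.553 with an estimated correlation), and 11 rose and 1 fell adjusted over the list alone. Tie1, an endothelial receptor kinase, stood at 694 ± 222 against 232 ± 123 normalised reads (1.75, limma adjusted p = 0.23), Pecam1, an endothelial junction protein, at 1095 ± 237 against 594 ± 164 (0.90, 0.23), and Esam at 528 ± 157 against 204 ± 90.0 (1.47, 0.23). Of these markers 6 rose in the authors' deposited table. The mean score of the list was 0.677 to 1.32 in the knockout libraries and -1.01 to 0.654 in the wild type libraries, lowest in library 1. The 21 macrophage and monocyte markers all had a fold change above 0 (median 0.44, camera adjusted p = 1.01e-11; adjusted p = 0.401 with an estimated correlation), and 16 rose adjusted over the list alone. Msr1, a scavenger receptor, stood at 207 ± 34.4 against 134 ± 5.33 (0.61, limma adjusted p = 0.229) and Csf1r, the receptor of macrophage growth factor, at 3098 ± 591 against 2261 ± 161 (0.44, 0.277). Neutrophil markers rose (median 0.41, 14 of 14 above 0, camera adjusted p = 5.82e-07; adjusted p = 0.595 with an estimated correlation), 5 of them adjusted over the list alone. Mpo, the myeloperoxidase of neutrophil granules, stood at 71258 ± 8922 against 44554 ± 16780 (0.74, limma adjusted p = 0.305) and Prtn3 at 6292 ± 586 against 4114 ± 1203 (0.65, 0.251). Erythroid and megakaryocyte markers rose (median 0.44, 15 of 17 above 0, camera adjusted p = 0.00146; adjusted p = 0.595 with an estimated correlation), including the erythroid regulator Klf1 (0.49). Their camera adjusted p was 0.0557 without wild type library 1, whose list score was -0.64 against 0.179 to 0.243 in the other wild type libraries.

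**Figure D3:**
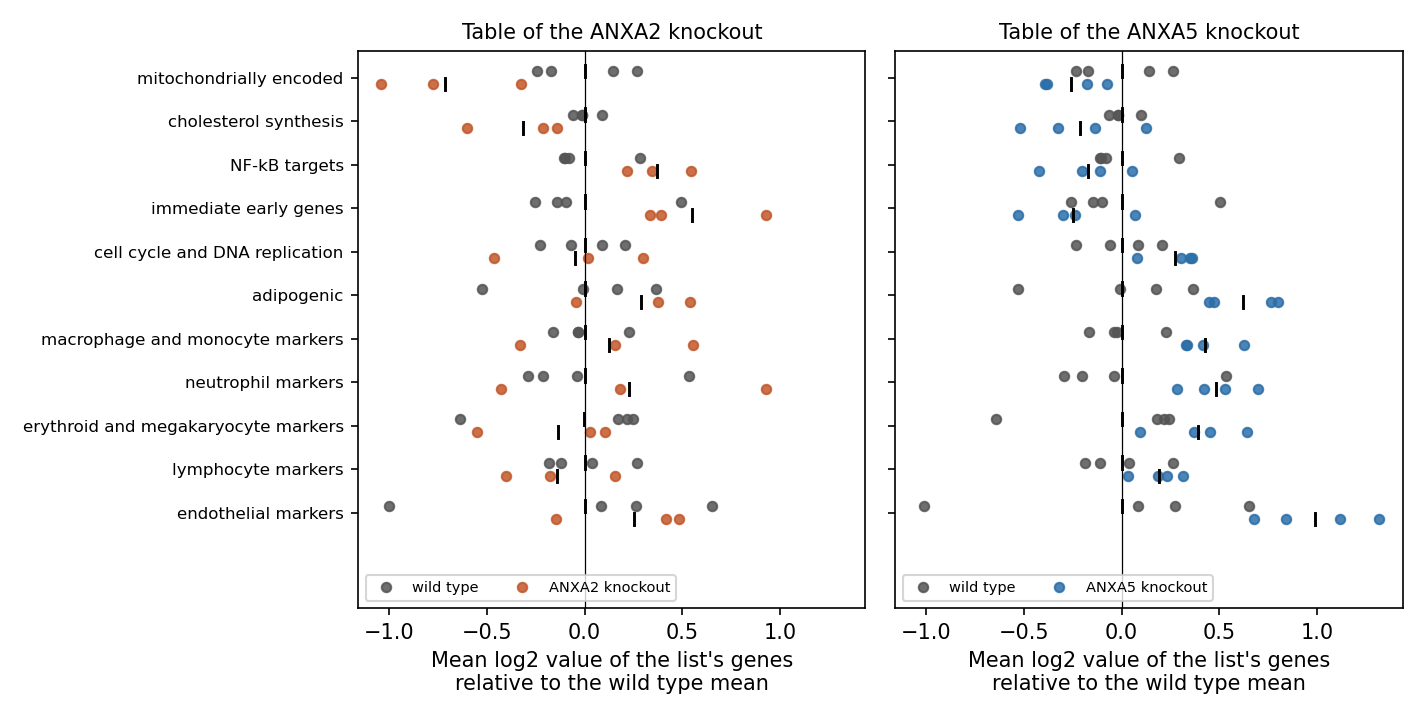
Mean log2 value over the genes of 11 lists, relative to the wild type mean, in each library of the ANXA2 knockout table (left) and the ANXA5 knockout table (right), with points for libraries and black ticks for group means. Endothelial markers lie between 0.677 and 1.32 in the ANXA5 knockout libraries and between -1.01 and 0.654 in the wild type, and mitochondrially encoded genes lie between -1.04 and -0.323 in the ANXA2 knockout.

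Antigen presentation, adipogenic and cell cycle lists rose beside these cell markers. Cell cycle and DNA replication genes were above 0 in 28 of 28 cases (median 0.29, camera adjusted p = 4.66e-10; adjusted p = 0.595 with an estimated correlation). Top2a, the topoisomerase of dividing cells, stood at 3574 ± 299 against 2878 ± 303 normalised reads (0.31, limma adjusted p = 0.311) and Ccne2, a cyclin of S phase entry, at 734 ± 102 against 543 ± 22.2 (0.42, 0.232). The adipogenic list had a median of 0.40 with 12 of 13 above 0 (camera adjusted p = 0.00118; adjusted p = 0.45 with an estimated correlation), and 3 rose adjusted over the list alone. The fatty acid binding protein gene Fabp4, also expressed by endothelium, stood at 1077 ± 263 against 406 ± 238 (1.58, limma adjusted p = 0.23) and Adipoq, which encodes adiponectin, at 556 ± 192 against 219.5 ± 107 (limma adjusted p = 0.266). Antigen presentation genes had a median of 0.18 with 14 of 17 above 0 (camera adjusted p = 0.000457; adjusted p = 0.401 with an estimated correlation), and 1 rose adjusted over the list alone. Cd74, the class II invariant chain and also a macrophage marker here, stood at 16553 ± 2455 against 11861 ± 1014 (0.47, limma adjusted p = 0.23). Actin and contractile genes rose (median 0.31, 16 of 19 above 0, camera adjusted p = 0.0313; adjusted p = 0.595 with an estimated correlation), with smooth muscle myosin Myh11 at 1.46. Genes of the unfolded protein response rose (median 0.11, 16 of 20 above 0, camera adjusted p = 0.0363; adjusted p = 0.595 with an estimated correlation), 2 of them adjusted over the list alone, with Sdf2l1 at 1878 ± 82.4 against 1391 ± 75.3 (0.43, limma adjusted p = 0.173). The call was lost without 3 of the 8 libraries for the actin list (limma camera adjusted p = 0.158 without wild type library 2) and without 5 for the unfolded protein response (0.137 without wild type library 4).

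Gene lists also fell in the ANXA5 knockout. Hox and positional genes, which mark the body region of origin, had a median of -0.33 with 4 of 21 above 0 (camera adjusted p = 0.00146; adjusted p = 0.401 with an estimated correlation), with the hindlimb gene Pitx1 at 103 ± 19.2 against 418 ± 269 normalised reads (-1.67, limma adjusted p = 0.319) and Hoxa11 at 76.5 ± 22.0 against 131 ± 25.3 (-0.79, 0.278). Plasminogen and coagulation genes had a median of -0.20 with 4 of 18 above 0 (camera adjusted p = 0.0129; adjusted p = 0.45 with an estimated correlation), and 2 fell adjusted over the list alone. The plasminogen activators Plat, at 4159 ± 276 against 6229 ± 1304 (-0.56, limma adjusted p = 0.23), and Plau, at 228 ± 100.2 against 455 ± 106 (-1.08, 0.266), had the smallest p. Immediate early genes had a median of -0.22 with 2 of 20 above 0 (camera adjusted p = 0.00118; adjusted p = 0.595 with an estimated correlation), with Fos at -0.51 and Zfp36, which destabilises cytokine messages, at -0.62. NF-kB targets had a median of -0.16 with 3 of 16 above 0 (camera adjusted p = 0.022; adjusted p = 0.595 with an estimated correlation), with Icam1 at 7437 ± 1227 against 10043 ± 1903 (-0.43) and Irf1 at -0.63. Cytokines and chemokines had a median of -0.22 with 6 of 23 above 0 (camera adjusted p = 0.0363; adjusted p = 0.595 with an estimated correlation), with Il6 at -0.64. Cholesterol synthesis genes had a median of -0.26 with 4 of 22 above 0 (camera adjusted p = 0.00216; adjusted p = 0.595 with an estimated correlation), with Sc5d at -0.30. Mitochondrially encoded genes had a median of -0.22 with 0 of 10 above 0 (camera adjusted p = 0.0017; adjusted p = 0.595 with an estimated correlation), with mt-Co1 at -0.45. The plasminogen and coagulation call was lost without 1 of the 8 libraries, the NF-kB and cytokine calls without 3 each, at a camera adjusted p of up to 0.0769, 0.292 and 0.128 (each without knockout library 3). The immediate early call was lost without 2, at up to 0.19 without wild type library 3, which had a list score of 0.503 against -0.26 to -0.0982 in the other wild type libraries. The cholesterol synthesis call was lost without knockout library 1 (limma camera adjusted p = 0.121).

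Annexins and S100 partners did not change as a list in the ANXA5 knockout (13 tested, camera adjusted p = 0.206), and 0 passed limma, 3 with an unadjusted p under 0.05. Anxa4 stood at 4464 ± 334 against 5275 ± 421 normalised reads (-0.24, limma adjusted p = 0.353), S100a11 at 9894 ± 1381 against 7965 ± 836 (0.31, 0.364) and Anxa3 at 4602 ± 139.5 against 5930 ± 1406 (-0.34, 0.388). Stromal identity markers had a camera adjusted p of 0.391 and 1 rise adjusted over the list alone, the pericyte marker Mcam at 181 ± 12.2 against 109.7 ± 22.1 (0.73, limma adjusted p = 0.227). Osteogenic genes had 0.0659 with a median of 0.40. The osteocyte gene Dmp1 stood at 143 ± 76.0 against 33.6 ± 6.52 (1.90, limma adjusted p = 0.217) and Bmp4 at 1001 ± 43.6 against 1412 ± 288 (-0.47, 0.279), and 1 gene rose and 1 fell adjusted over the list alone. Skeletal muscle markers had 0.0527 (median -0.59, Acta1 at -1.10) and lymphocyte markers 0.0826 (median 0.07, Igkc at 9812 ± 3152 against 5492 ± 1096).

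Matrix proteases had a camera adjusted p of 0.0675, glycolysis and hypoxia 0.0921, endosome and lysosome 0.116, TGF-beta and BMP targets 0.116, the Wnt pathway 0.123 and ribosomal proteins 0.135 in the ANXA5 knockout. Nkd2, an inhibitor of Wnt signalling, was the 1 Wnt gene that fell adjusted over the list alone (-0.61, limma adjusted p = 0.23). Apoptosis and efferocytosis had 0.156, collagens 0.226, interferon response 0.226, calcium handling 0.29, mitochondrial biogenesis 0.292, nuclear oxidative phosphorylation 0.493 and NRF2 targets 0.961. In 7 further lists the median, the mean and the direction of the test differed in sign. Chondrogenic genes (median -0.07, mean 0.03, limma camera adjusted p = 0.52), angiogenic factors (-0.07, 0.15, 0.967), membrane repair genes (-0.02, 0.05, 0.591) and extracellular vesicle genes (-0.01, 0.03, 0.961) were tested as lower. Immunomodulatory mediators (0.03, 0.02, 0.476), focal adhesion genes (0.01, 0.06, 0.961) and p53 targets (0.00, -0.05, 0.292) were tested as lower too. Zmat3, which lies on chromosome 3 with Anxa5, was the 1 p53 gene that fell adjusted over the list alone. Of the other lists, 3 angiogenic factors rose adjusted over the list alone, including Angptl4 at 3871 ± 639 against 1719 ± 453 normalised reads (1.19, limma adjusted p = 0.146). For the mediators, 1 rose and 1 fell adjusted over the list alone: nitric oxide synthase gene Nos2 stood at 42.5 ± 1.90 against 15.6 ± 8.38 (1.59, limma adjusted p = 0.245) and the cyclooxygenase gene Ptgs2 at 2508 ± 682 against 4859 ± 1635 (-0.93, 0.266). Over all 41 tested lists 16 passed camera, 9 upward and 7 downward. With an estimated correlation camera called 0 (lowest adjusted p = 0.401, and 3 at an unadjusted p under 0.05), and fry called 0 (lowest adjusted p = 0.103). Of 756 distinct genes in these lists, limma over all genes called 0, 166 had an unadjusted p under 0.05, edgeR called 0 and DESeq2 called 30, against 51 list entries that passed adjusted over the list alone. Of the 16 lists, 8 kept their call without each library in turn.

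Over the 15934 genes tested in both comparisons, 0 were called by limma in both, from 14 calls in the ANXA2 knockout and 4 in the ANXA5 knockout. Independent lists would share 0.0011 higher and 5e-04 lower genes, which takes no account of the shared wild type libraries, and 0 were shared by edgeR. Both comparisons of the authors' deposited table called 11 genes, 10 higher and 1 lower, and how many the shared wild type libraries alone would give was not tested. In the authors' deposited table these included the antisense transcript Rab10os (log2 fold change 1.07 in the ANXA2 and 0.76 in the ANXA5 knockout), the clock gene Per1 (1.30 and 1.22) and the glucocorticoid-induced gene Tsc22d3 (1.14 and 1.98). They also included, in the authors' deposited table, the macrophage gene Mpeg1 (1.495 and 1.08), the cell cycle kinase Wee1 (0.89 and 0.98) and, lower, the purine receptor P2ry1 (-0.62 and -0.43). The immunoglobulin segments Ighv8-8 (1.46 and 2.60), Igkv3-4 (2.91 and 2.17) and Igkv5-43 (3.26 and 2.46) were among the 11 as well. These genes were chosen after their values were seen. Log2 fold changes correlated across genes at 0.413 (Spearman 0.391), where 100 simulations of unchanged groups against the same wild type libraries gave 0.463. Their covariance was 0.0455 against a simulated 0.0325, a difference of 0.0129. When the wild type libraries were divided between the comparisons, the correlation averaged 0.0945 over 6 divisions (-0.0704 to 0.286) and the covariance 0.0113 (-0.0109 to 0.0335).

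The effects of both knockouts differed in 41 of 15936 genes in a joint edgeR fit of the recovered reads, with 24 higher and 17 lower in the ANXA2 than in the ANXA5 knockout and 2230 at an unadjusted p under 0.05. Icam1, the leukocyte adhesion molecule, was higher in the ANXA2 knockout, at 570.1 ± 86.1 against 259 ± 42.9 CPM (log2 1.14, edgeR adjusted p = 0.0171). Id3, a target of BMP signalling (0.93, edgeR adjusted p = 0.0324), the protease gene Adamts4 (1.67, 0.0346) and the p53 target Zmat3 (0.93, 0.0346) were higher as well, and the proteoglycan gene Vcan was lower (-0.62, 0.0345). Anxa5 (3.48) and Anxa2 (-1.82) were among the 41. Besides the targets, these genes were chosen after their values were seen. Of the 41 genes, 17 lay on chromosome 9, Icam1 among them, while Zmat3 lay on chromosome 3 with Anxa5. Of the 41, 11 were also called in the ANXA2 and 3 in the ANXA5 comparison. DESeq2 called 395 genes. The edgeR count was 15 without ANXA2 knockout library 1, 22 without library 3, 26 without wild type library 4, and 17, 24, 17 and 18 without ANXA5 knockout libraries 1 to 4. Lower genes then outnumbered higher ones in several of these fits, with 6 higher and 9 lower without ANXA2 knockout library 1 and 7 and 10, 11 and 13, 7 and 10, and 5 and 13 without ANXA5 knockout libraries 1 to 4.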

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

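The regroupings without the targeted genes, the tests of position and the tests without wild type library 1 and against lymphocyte markers were chosen after the result was seen. Of 154 groups of 4 values examined for a single library apart from the rest, 17 contained such a library, and chance flags about 1 in 20 groups. The wild type libraries occur in both tables, so several of these values are the same library seen again.

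Among genes, Plac9a stood at 3836 normalised reads in wild type library 1 against 2924 to 3076 in the other wild type libraries, and Lrmda at 15.89 against 5.822 to 7.461. Igkv5-43 stood at 11.61 in wild type library 2 against 3.493 to 4.238. Among the mean scores of lists in the table of the ANXA2 knockout, wild type library 3 stood apart in NF-kB targets (0.285), p53 and senescence (0.0669) and ribosomal proteins (-0.376). Wild type library 4 stood apart in Hox and positional genes (-0.277) and wild type library 1 in erythroid and megakaryocyte markers (-0.635). In the table of the ANXA5 knockout the same libraries gave 0.294, 0.0763, -0.366, -0.279 and -0.64, and wild type library 1 also stood apart in antigen presentation (-0.113 against 0.0275 to 0.0501). ANXA5 knockout library 2 had a score of 0.0712 for cytokines and chemokines against -0.371 to -0.339. ANXA5 knockout library 3 had -0.0919 for glycolysis and hypoxia against 0.125 to 0.168, and -0.246 for TGF-beta and BMP targets against 0.00993 to 0.0557. The cause was not tested. Genes that differed between both knockouts numbered 41.

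All regroupings of the libraries were fitted as well. For the 18 genes of the ANXA2 knockout, 1 of 35 groupings, the real one, gave as many, and the highest other gave 1. For the 5 genes of the ANXA5 knockout it was 1 of 35 with 0 as the highest other, and for the 41 genes of the difference 1 of 35 with 1 as the highest other. Since the deletion alone gives the real grouping a call, the counts were repeated without the targeted genes: 17 genes in the ANXA2 knockout (highest other 1), 4 in the ANXA5 knockout (0) and 38 for the difference (1), each reached by 1 of 35 groupings. A chance division of these libraries was thus unlikely to give these counts, although 1 of 35 is the smallest share these groups allow. Called genes close to the target in the genome, such as Mccc1, were left in. The labels do not state separate animals or cultures, so a chance difference between those behind each group was not excluded. For the 16 lists of the ANXA2 knockout 9 of 35 groupings gave as many and the highest other gave 18, and for the 16 lists of the ANXA5 knockout it was 5 of 35 with 19. Chance could not be excluded for the number of lists in either knockout.

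Called genes of the ANXA2 knockout gathered on chromosome 9. Genes within 5 Mb of Anxa2, 0 of them called, passed an unadjusted p of 0.01 more often than genes of other chromosomes (12.2% against 1.65%, Fisher's exact p = 1.26e-06). An effect of the missing protein that takes no account of position would not by itself give this excess near Anxa2. The test holds none of the called genes and takes neighbouring genes as independent, so it did not exclude such an effect for the calls on chromosome 9. Such an effect stayed open too for the 9 of 16 calls with a position on other chromosomes. These were not evenly spread: Plac9a, Tmem254a and Lrmda lay on chromosome 14, Erdr1 on X and Gm47283 on Y in the annotation used. Gm47283 was not higher in wild type libraries 3 and 4, with low Xist (58.2 and 74.8 normalised reads), than in libraries 1 and 2, with high Xist (107 and 139). Its place on Y is thus uncertain, and whether Erdr1 and Gm47283 are separate calls was not tested. A gathering on chromosome 14 was not tested. DNA of a donor strain carried along with the targeted gene may account for part of the calls on chromosome 9, since it would leave the same excess, and genes near Anxa5 had one too (Fisher's exact p = 0.000105). The labels give no breeding history, and a local effect of the targeted allele on its neighbours could leave the same trace near the gene.

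Endothelial markers rose as a list in the ANXA5 knockout with the preset correlation, without a call at an estimated correlation (camera adjusted p = 0.553) and with 0 of 17 past limma over all genes (12 at an unadjusted p under 0.05, 0 by edgeR, 6 by DESeq2) and 6 in the authors' deposited table. Without the low wild type library 1 the list median was 0.787 in place of 1.18, so the rise was smaller but did not vanish. That median was not tested over libraries, so a part played by library 1 was not excluded. A lower share of stromal cells that raises all other cell types alike would give similar medians. Endothelial and lymphocyte medians differed (1.18 against 0.0685, permutation p = 0.00011), and the macrophage, neutrophil and erythroid lists lay between at 0.439, 0.41 and 0.439. The permutation shuffled genes of the same libraries as if they were independent, so it could not exclude a lower stromal share. Of 16 further endothelial genes, chosen beforehand, 87.5% were higher, with a median log2 fold change of 0.502 and a smallest limma adjusted p of 0.273. More endothelial cells or their RNA in the knockout cultures could give such a rise. These genes were read in the same libraries as the list, so they are not independent evidence for it.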

How the results depend on the processing

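The Xist covariate, the fits without several libraries and the unadjusted threshold near the targets were chosen after the result was seen. With DESeq2 the genes changed numbered 107 in the ANXA2 and 278 in the ANXA5 knockout in place of 18 and 5, and 395 in place of 41 for their difference. With Xist as a covariate 284 genes passed in the ANXA2 knockout (248 higher) and 6 in the ANXA5 knockout. Without a library in turn the ANXA2 count ran from 8 (without knockout library 3) to 16 (without knockout library 4), with 10 without wild type library 4 and 11 without wild type library 2. The ANXA5 count ran from 4 (without knockout library 1) to 32 (without wild type library 4), with 8 without knockout library 3. The difference ran from 15 (without ANXA2 knockout library 1) to 49 (without wild type library 1). The cause was not tested. With an estimated correlation 0 lists passed in the ANXA2 and 0 in the ANXA5 knockout in place of 16 and 16, and without a library in turn 12 to 19 and 13 to 20 passed. With the wild type divided between the comparisons their correlation averaged 0.0945 in place of 0.413. The division also left 2 wild type libraries in each comparison, so the cause was not tested. At an unadjusted p under 0.01, 12.2% of genes near Anxa2 passed. Other filters, pseudocounts, scalings and edgeR gave 17 to 21 and 4 to 5 genes. Of 139 named genes in the ANXA2 and 133 in the ANXA5 knockout, 0 called genes reversed.

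With the replicate number as a replicate block 8 genes passed in the ANXA5 knockout (6 higher, 4 shared with the fit without it) and 16 lists (15 shared). The numbers did not pair the libraries: equal numbers correlated at 0.049, -0.075, -0.25 and 0.067, and other numbers at up to 0.1, 0.14, 0.25 and 0.13. For the ANXA2 knockout no fit paired by the numbers of the titles was made, because its columns could not be matched to the titles.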

Other observations

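The tests of clock and glucocorticoid genes were fixed before their values were seen, while the genes in the next paragraphs were chosen after the result was seen. Some genes known from endothelium were among the 158 higher in the ANXA5 knockout in the authors' deposited table, and 0 of those named here passed limma (adjusted p of 0.117 to 0.217). The gap junction gene Gja5 had a log2 fold change of 2.48 (adjusted p = 8.37e-08), the receptor gene Notch4 2.08 (1.67e-06) and the endothelial nitric oxide synthase gene Nos3 2.06 (0.000124) in the authors' deposited table. Sema3g (2.09) and Gpihbp1, which carries lipoprotein lipase across capillaries (2.14), passed in the authors' deposited table as well, and the fibroblast gene Pi16 was lower there (-1.10).

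Among the 41 genes that differed between the knockouts in the joint edgeR fit, 3 belong to the breakdown of branched-chain amino acids, a process for which no list was tested. Pccb, a subunit of propionyl-CoA carboxylase, was higher in the ANXA2 than in the ANXA5 knockout by 1.23 on the log2 scale (edgeR adjusted p = 0.000979), Bckdhb, a subunit of the branched-chain keto acid dehydrogenase, by 1.42 (0.00106) and Mccc1 by 0.79 (0.0198). Pccb and Bckdhb lie on chromosome 9 with Anxa2, and Mccc1 on chromosome 3 with Anxa5, so position may play a part. This was not tested for the genes of the edgeR difference. In the authors' deposited table the ANXA2 knockout also had lower Aldh1a2, a gene of retinoic acid synthesis also on chromosome 9 (-1.57, adjusted p = 0.000651), and lower Vcan, a large matrix proteoglycan (-0.57, 3.87e-05).

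The clock gene Per1 (1.30 and 1.22) and the clock-controlled gene Wee1 were higher in both knockouts in the authors' deposited table. Per2, Per3 and Tef were higher in the ANXA2 knockout and did not pass in the ANXA5 knockout (adjusted p = 0.083, 0.455 and 0.413 in the authors' deposited table). Npas2, a core clock gene, was lower in the ANXA5 knockout (-0.61, adjusted p = 0.0201) and did not pass in the ANXA2 knockout (-0.50, adjusted p = 0.258) in the authors' deposited table. Of these 6 genes 0 passed limma in either knockout, and 0 were among the 41 genes of the edgeR difference, so a difference between the knockouts was not shown. Wee1 stood at 2187, 1519, 1305 and 2384 normalised reads in ANXA5 knockout libraries 1 to 4 and at 976.8, 892.8, 956.9 and 920.5 in the wild type, and the glucocorticoid-induced gene Tsc22d3 at 31340, 14010, 7426 and 24260 against 4855, 3714, 6463 and 4502. In ANXA2 knockout libraries 1, 3 and 4 Wee1 stood at 1895, 1785 and 1052 against 815.7 to 893.1 in the wild type. Tsc22d3 stood there at 10770, 13440 and 5088 against 3393 to 5852, so knockout library 4 lay within the wild type range. A clock phase that differed at harvest could raise such genes. An index of 8 other clock genes was the mean of output genes minus the mean of genes of opposite phase. This index was higher by 0.467 in the ANXA2 (exact permutation p = 0.0857) and by 0.389 in the ANXA5 knockout (exact permutation p = 0.171). A difference in glucocorticoid exposure could raise such genes too, and the mean of 6 other induced genes was higher by 0.655 (exact permutation p = 0.114) and 0.74 (exact permutation p = 0.0857). These tests left both possibilities undecided.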
